A study of Homo sapiens with 9 samples.

How the data were processed

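The deposited files held 9 dual-colour Agilent whole human genome arrays and 1 table of fold changes. Total RNA came from Calu6 tumours grown in the lungs of nude rats: 1 pool of untreated tumours from 4 animals, 4 azacytidine tumours and 4 tumours given azacytidine plus MS-275, per the labels. Each RNA was hybridised on 2 arrays, once per dye, so that the 9 arrays closed a loop; arrays 1 to 4, arrays 5 to 8 and array 9 lay on 3 slides.

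The array files hold the mean intensity of each spot and the median intensity of its local background for both dyes, without normalization, per the file headers. They also hold processed intensities that Agilent Feature Extraction 10.5.1.1 had background-subtracted, detrended and dye-normalized, per the file headers. The deposited table holds log2 ratios of each tumour over the untreated pool, 1 per spot. The labels name limma and Feature Extraction as the processing tools; the background method and the model behind the table are not stated. Its values correlated with the loop levels computed here, across detected probes, with r from 0.998 to 1.00, and were used only for that check. Probe coordinates are those of the files, on hg18.

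Mean signals were background-corrected with normexp (offset 50) and loess-normalized within arrays, with weight 0 for control spots, in limma 3.58.1 (statmod 1.5.0, R 4.3.3). Spots that Feature Extraction marked as outliers were left out and spots of a probe were averaged. Of 41000 probes, 26773 were kept because they were well above background in the pool, or in at least 3 of the 4 tumours of a treatment. Probes were named through their RefSeq accessions with a table of assembly GRCh38.p14, used for names only (25398 probes), through the symbol (2510), through an unambiguous synonym (789) or by the name in the file (514), and 11789 had no gene name. The brightest kept probe stood for a gene, which gave 13994 genes. Of the 5336 genes with several kept probes, 1649 were called for azacytidine against the pool, and in 233 of these the probes differed in sign; for the combination against azacytidine this held for 105 of 945.

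The median signal per array and dye ran from 51.8 to 75.3 in Cy5 and from 38.2 to 60.3 in Cy3, with median local backgrounds of 30.5 to 32.5 and 15.5 to 20.5. No read depth applies to arrays, and their number limits the precision: the median standard error of a log2 fold change was 0.130 for each treatment against the pool and 0.119 between treatments. The human probes were not tested for binding of rat transcripts.

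Log2 ratios of the 9 arrays were fitted by generalized least squares with a term per treatment and a dye term. The covariance held a component for each RNA, shared by its 2 arrays, and a component for each array; the share of the first, estimated by restricted maximum likelihood over all probes, was 0.300. Limma's empirical Bayes moderated test with 6 residual degrees of freedom was followed by Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The pool counted as 1 sample. This fit gives most weight to the tumours hybridised beside another group, so for several genes and lists the mean and standard deviation of the 4 tumours' loop levels, each with the same weight, are given beside the fitted value. In azacytidine against the pool, combination tumours 1 and 4 also entered with weights of -26.7% and 26.7%, and azacytidine tumours 4 and 1 likewise in the combination against the pool. What the codes mark is not given in the sources used here. If tumours that share a code are not independent, n = 4 stands for 2 codes in the azacytidine group and 3 in the combination group.

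The gene lists, 33 in number, were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. They covered cell types, pathways, epigenetic regulators and host cells, and 32 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over lists. The list of erythroid markers, with 3 measured genes, was not tested. Camera with an estimated correlation called 0 lists in each comparison (lowest adjusted p 0.495, 0.642 and 0.535); fry, which tests whether a list's genes move one way on balance, called 14, 2 and 13.

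Genes named here follow a rule, apart from SMARCA4, HMGA2 and NES: per comparison the up to 12 largest rises and falls among called genes whose 4 tumours lay on one side of the pool (or did not overlap the other treatment), up to 4 members per list with the smallest p, and 10 fixed genes. The rule gave 295 genes, of which 125 were picked for description after their values were seen, and 2 more, picked in the same way, are not reported here. Levels of sex-linked marker genes were not examined. The overlap of the 2 comparisons with the pool was set against data simulated with no effect and the same shared pool.

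The fit was tested on 5 simulated data sets with changes of known size. For azacytidine against the pool 34.9%, 77.9% and 96.7% of changes of 0.5, 1 and 2 log2 units were recovered, for the combination against the pool 32.5%, 70.7% and 93.9%, and for the combination against azacytidine 46.5%, 85.4% and 98.0%. False calls made up 3.81% to 5.76% of the calls, and data with no change gave 0 calls on average. The data sets were drawn from the fitted model itself, with genes independent and tumours of equal variance. These rates therefore hold only under that model and are not those of the real calls.

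Alternatives were the processed signals, no background subtraction, median centring, no detection filter, detection in all 9 RNAs, outlier spots kept, independent arrays, separate channels, no dye term, a pool with the variance of a mean of 4 tumours, averages of tumours that share a code, a trended robust prior, the mean of a gene's probes, slide terms, the number in the codes as a block, and leaving out each tumour in turn. After the data were seen 4 more were added: azacytidine tumours 2 and 3 as 1 sample, tumours weighted equally, and each of the first 2 slides alone. Equal weights and averages over codes treat the loop levels as independent values, although these share arrays and the pool. Their p-values and counts do not allow for this sharing. With slide terms or within a slide, only array 1 sets azacytidine tumours against the pool. Only array 5 then sets the treatments against each other. With slide terms no array sets combination tumours against the pool, since array 9 lay alone on its slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.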

Results

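Gene expression was measured in orthotopic lung tumours of Calu6, a human lung cancer cell line, grown in nude rats. The series title names gene re-expression after epigenetic therapy, and the comparisons ask which transcripts differ after azacytidine, a cytidine analogue that blocks DNA methyltransferases, alone or with MS-275 (entinostat), an inhibitor of class I histone deacetylases. The 9 RNAs were 1 pool of 4 untreated tumours, 4 azacytidine tumours and 4 tumours given both agents, here called combination tumours. They were hybridised on 9 dual-colour arrays in a closed loop, each RNA once with Cy5 and once with Cy3, with the pool placed between azacytidine tumour 1 and combination tumour 4. Between 59.0% and 68.7% of the probes were well above background in each channel of each array. The number of arrays, and the 1 untreated RNA, limit the precision of every comparison.

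Across genes, which are not independent replicates, the levels over the pool correlated with r from 0.819 to 0.971 between azacytidine tumours and from 0.568 to 0.884 between combination tumours. All levels share the 1 pool, and simulated data with no effect gave average r from 0.410 to 0.739 and from 0.416 to 0.743 for these pairs. The r exceeded its simulated value in each of the 6 azacytidine pairs, by 0.168 to 0.423, and in each of the 6 combination pairs, by 0.0424 to 0.293. Combination tumours 1, 2 and 3 correlated with the azacytidine tumours at 0.0502 to 0.330, below the simulated value in each pair. Combination tumour 4 lay between the groups: its r was 0.568 to 0.677 with the other combination tumours and 0.480 to 0.622 with the azacytidine tumours, above the simulated values of 0.244 to 0.355. The excess over the simulated value was 0.236 to 0.302 with the azacytidine tumours and 0.0614 to 0.152 with its own group. The median over genes of the standard deviation between the 4 tumours was 0.118 log2 units for azacytidine and 0.0974 for the combination. In the first principal component, with 74.8% of the variance, the pool scored -17.2, the azacytidine tumours 53.6, 23.6, 22.1 and 13.1, and the combination tumours -30.0, -25.0, -29.1 and -11.2.

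After azacytidine, the lists of neuronal, imprinted, mesenchymal and proliferation genes lay above the untreated pool and those of epithelial, antigen-presentation and p53-target genes below it, by camera with a preset correlation. Many members of these lists did not pass, and 0 lists were called with an estimated correlation. Fitted fold changes are given with their SE; tumour means over the pool weight the 4 tumours of a treatment equally and are given with their SD (n = 4). The largest rise was in NEFM, a neurofilament subunit (probe on chromosome 8 from 24831089 to 24831148, hg18), which was 23.9-fold higher (log2 fold change 4.58 ± 0.55, SE, adjusted p 0.00621). Its level over the pool was 3.69 ± 0.73 (SD, n = 4). SPARC, a matrix glycoprotein, rose 19.9-fold, GAL, which encodes the neuropeptide galanin, rose 17.4-fold, and IGF2, an imprinted growth factor, rose 15.6-fold. Their tumour means were lower than these fits, at 3.56 ± 0.72, 3.62 ± 0.72 and 3.12 ± 0.72 on the log2 scale. The fit gave most weight to azacytidine tumour 1, the highest of the 4 for each, and also drew on combination tumours 1 and 4. The largest fall was in SPINK4, a protease inhibitor of mucosal secretions (chromosome 9, 33236720 to 33238476), with a log2 fold change of -3.65 ± 0.60 and an adjusted p of 0.00748. Of 13994 genes tested, 4077 changed, 2586 up and 1491 down. In each of the called genes the 4 azacytidine tumours lay on the same side of the pool. Their levels share the 1 pool and some arrays, so they are not 4 independent values. Of the called genes, 848 (642 up and 206 down) changed at least 2-fold.

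Proliferation genes rose as a group after azacytidine: 29 of 47 measured members rose, 1 fell and 17 did not pass the test, with a median log2 fold change of 0.80 (camera adjusted p 1.68e-07, 33 up and 1 down adjusted over the list alone). The call of the list was lost at an adjusted p = 0.511 with an estimated correlation. In azacytidine tumours 1 to 4 the list medians were 1.01, 0.45, 0.37 and 0.26, so that the fitted median lay above 3 of the 4 tumours. Among its genes GINS2, a replication factor, rose by 1.88 ± 0.36 (tumour mean 1.37 ± 0.51) and NDC80, a kinetochore protein, by 1.56 ± 0.30. Of 77 cytosolic ribosomal protein genes, 25 rose and none fell, with a median of 0.34 (adjusted p 8.82e-06, 27 up adjusted over the list alone), for example RPL24 at 0.67 ± 0.12, against a mean of the tumours' list medians of 0.18 ± 0.12. This list had an adjusted p = 0.511 with an estimated correlation. Hypoxia and glycolysis genes had 18 of 40 members up and 2 down, with a median of 0.40 (adjusted p 0.000817, 19 up and 2 down adjusted over the list alone) and a mean of tumour medians of 0.31 ± 0.09. They had an adjusted p = 0.495 with an estimated correlation. HK2, which encodes a hexokinase, rose by 2.51 ± 0.39 and PDK1, which restrains pyruvate oxidation, by 1.44 ± 0.22. This list lost its call within the 4 arrays of the first slide, with slide terms in the fit, and without combination replicate 4.

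Neuronal genes had 22 of 35 measured members up and 3 down after azacytidine, with a median log2 fold change of 0.79 (adjusted p 4.82e-05, 25 up and 4 down adjusted over the list alone), at an adjusted p = 0.495 with an estimated correlation. The tumour medians were 1.01 in tumour 1 and 0.39 to 0.54 in the others. SCG3 and CHGA, proteins of secretory granules, rose by 2.39 ± 0.33 and 2.15 ± 0.31. Imprinted genes had 11 of 21 members up and none down, with a median of 0.60 (adjusted p 0.00193, 12 up and 1 down adjusted over the list alone), at an adjusted p = 0.495 with an estimated correlation. The mean of the tumour medians was 0.44 ± 0.19. MAGEL2 rose by 2.76 ± 0.41 and PEG10 by 1.98 ± 0.31, and the call of the list was lost without aza replicate 1. Mesenchymal genes had 11 of 26 members up and 1 down, with a median of 0.33 (adjusted p 0.0151, 12 up and 2 down adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). The transcription factor gene SNAI2 rose by 1.32 ± 0.17 and TNC, a matrix glycoprotein, by 2.03 ± 0.32. The list lost its call with median centring and without aza replicate 1. Host fibroblast markers, which tumour cells can also express, had 4 of 14 members up, COL6A1 at 2.30 ± 0.38 among them, and did not pass as a list (adjusted p 0.152). With slide terms and within the first slide this list was called higher (adjusted p 0.00688 and 0.00695), host lymphoid markers lower (adjusted p 0.0301 and 0.0285) and host myeloid markers lower (adjusted p 0.0307 and 0.0334). In both settings only array 1, with azacytidine tumour 1, sets azacytidine against the pool.

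Epithelial genes had 11 of 30 measured members down and none up after azacytidine, with a median log2 fold change of -0.58 (adjusted p 4.82e-05, 11 down adjusted over the list alone), at an adjusted p = 0.495 with an estimated correlation. The tumour medians were -0.80 in tumour 1 and -0.26, -0.27 and -0.13 in tumours 2, 3 and 4, a mean of -0.37 ± 0.29. ESRP2, an epithelial splicing regulator, fell by 1.66 on the log2 scale, and CRB3, a polarity protein, fell by 0.83. Class I antigen-presentation genes had 6 of 22 members down, with a median of -0.39 (adjusted p 0.00141, 8 down adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). The tumour medians averaged -0.21 ± 0.15. The proteasome subunit gene PSMB8 fell by 1.53 and the peptide transporter gene TAP1 fell by 0.97. Of 8 class II genes, 3 fell, both over all genes and adjusted over the list alone, with a median of -0.64 (adjusted p 0.00669), at an adjusted p = 0.495 with an estimated correlation. CD74 was at -3.05 ± 0.72 and HLA-DRB1 at -2.93 ± 0.63 (both called), and the class II list lost its call without aza replicate 1. Markers of lung epithelium, which the rat host tissue could also contribute, moved with them. Of 13 such markers 6 fell, again 6 adjusted over the list alone, with a median of -0.36 (adjusted p 0.00949, adjusted p = 0.495 with an estimated correlation). SFTPC, a surfactant protein of alveolar cells, was at -3.37 ± 0.78 and CLDN18, a tight-junction protein, at -2.22 ± 0.49 (both called). The lung list lost its call without aza replicate 4.

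Of 29 p53 target genes, 10 fell and none rose after azacytidine, with a median log2 fold change of -0.35, which turned to 0.08 with median centring (adjusted p 0.000348, 1 up and 11 down adjusted over the list alone). For this list the adjusted p = 0.495 with an estimated correlation. GDF15, a stress cytokine, fell by 1.90 and FDXR, a mitochondrial reductase, fell by 1.26. Heat shock and unfolded-protein genes had 6 of 29 members down, with a median of -0.21, which turned to 0.19 with median centring (adjusted p 0.0424, 3 down adjusted over the list alone, adjusted p = 0.495 with an estimated correlation). The tumour medians averaged -0.11 ± 0.11. ATF3, a stress-induced transcription factor gene, was at -0.69 ± 0.15 (called). The call of the list was lost in 11 of the 15 settings compared for lists. Median centring put the median of all genes 0.32 above the pool, and both lists still lay below it.

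Germline antigens and genes with promoters often methylated in lung cancer held large rises, and their lists were not called by camera in the fit of all arrays. The cancer-testis list was called higher without background subtraction (adjusted p 0.0445) and without aza replicate 1 (adjusted p 0.00774). Fry, which does not compare a list with other genes, called both up (adjusted p 0.0109 and 0.0127), and also germ-cell and meiosis genes (adjusted p 0.00666). Of 14 measured cancer-testis antigens, 8 rose and 2 fell (camera adjusted p 0.0624, 8 up and 2 down adjusted over the list alone). CSAG2 rose by 3.08 ± 0.37 and MAGEB2 by 2.58 ± 0.39. In the promoter-methylation list 13 of 40 genes rose and 5 fell (adjusted p 0.590, 13 up and 8 down adjusted over the list alone). CDKN2A, which encodes cell-cycle inhibitors, rose 6.39-fold (2.68 ± 0.41, adjusted p 0.00683, tumour mean 2.03 ± 0.57) and DLC1 rose 3.19-fold. TIMP3 also rose, but only 1 of its 2 channels in the pool was well above background. The DNA methyltransferase genes DNMT1 and DNMT3B rose 2.12-fold and 2.15-fold, and DNMT3A rose by 1.68 ± 0.29. Their list of 17 had 6 up and 3 down (adjusted p 0.382, 6 up and 4 down adjusted over the list alone). HDAC2 rose by 1.07 ± 0.21 and BCL2L11, a pro-apoptotic gene, by 0.42 ± 0.09. HDAC1 at 0.17 ± 0.09, HDAC3 at 0.07 ± 0.10, CDKN1A at -0.72 ± 0.31 and BIK at -0.15 ± 0.35 did not pass.

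The test of azacytidine against the pool was limma's moderated test of the loop, in which azacytidine tumour 1 carried 57.9% of the weight of the azacytidine group, tumour 4 27.1%, tumour 2 9.51% and tumour 3 5.49%. Without aza replicate 1 limma called 0 genes (2825 at an unadjusted p under 0.05), and without aza replicate 3 it called 782. With separate channels 5 were called, with tumours weighted equally 1294, with median centring 1752, with Agilent processed signals 2595, with tumours that share a code averaged 1364 and with azacytidine tumours 2 and 3 as 1 sample 3356. With slide terms 5500 genes were called, and the 4 arrays of the first slide alone gave 5220. In both, only array 1, azacytidine tumour 1 with the pool, sets azacytidine against the pool. These counts therefore do not compare 4 tumours with the pool.

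**Figure D1:**
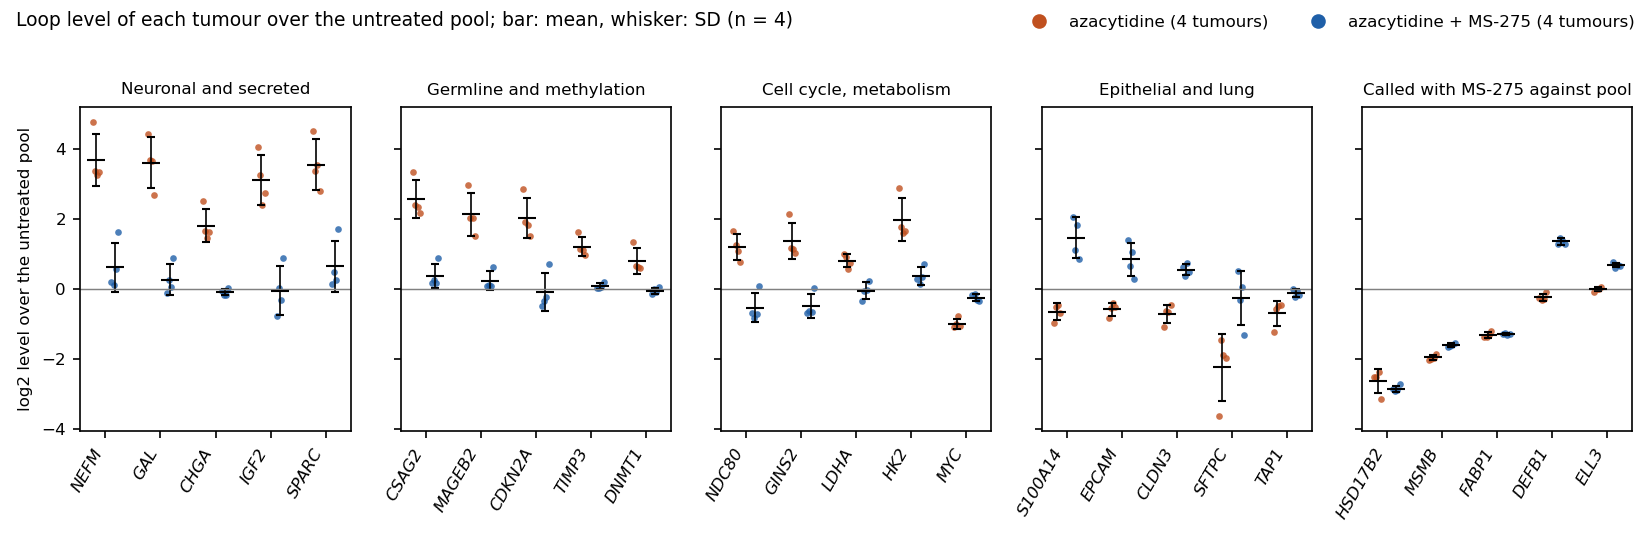
Log2 level of each tumour over the untreated pool (y axis) for genes named in the text (x axis), where points are the 4 tumours of each treatment, horizontal bars their mean and whiskers the SD (n = 4). NEFM averaged 3.69 in the azacytidine tumours and 0.62 in the combination tumours, whereas HSD17B2 averaged -2.64 and -2.85, and FABP1 and MSMB lay near background in the treated tumours.

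After azacytidine plus MS-275, few single genes were called against the pool. DEFB1, an epithelial antimicrobial peptide gene (chromosome 8, 6715591 to 6715650), was 2.39-fold higher (log2 fold change 1.26 ± 0.11, adjusted p 0.00950), at 1.36 ± 0.09 (SD, n = 4) over the pool. CASC15, a long non-coding RNA, rose by 1.00 ± 0.11, and MST1, PPP1R1C, EMP2 and ELL3 rose by 0.95, 0.87, 0.81 and 0.66. HSD17B2, a steroid dehydrogenase gene (chromosome 16, 80689398 to 80689457), was 6.21-fold lower (-2.63 ± 0.25, adjusted p 0.00950). SLC38A6, a transporter gene, fell by 0.96. FABP1, a fatty-acid binding protein of liver and gut, was not well above background in any combination channel, so that it was at least 2.19-fold lower than in the pool. MSMB, which encodes a secreted protein of prostate and mucosa, ANXA10 and CD3E, a T-cell marker, were also called lower. Only 3, 2 and 1 of their 8 combination channels were well above background, so the sizes of these falls are not given.

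In all, 12 genes passed for the combination against the pool, 6 up and 6 down, and 2347 had an unadjusted p under 0.05. The fixed genes did not pass in this comparison. BIK was at 0.91 ± 0.35, CDKN2A at 0.61 ± 0.41, CDKN1A at 0.19 ± 0.31 and BCL2L11 at 0.57 ± 0.09 (adjusted p 0.0899). DNMT1 was at 0.19 ± 0.24, DNMT3A at 0.55 ± 0.29, DNMT3B at 0.57 ± 0.20, HDAC1 at 0.33 ± 0.09, HDAC2 at 0.32 ± 0.21 and HDAC3 at 0.19 ± 0.10.

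By camera 7 lists were called in the combination tumours against the pool. The 56 oxidative phosphorylation genes had a median of -0.24 (adjusted p 3.93e-11, 1 down adjusted over the list alone) with no member passing over all genes. For the list the adjusted p = 0.642 with an estimated correlation. NDUFS8, of respiratory complex I, was at -0.42 ± 0.08. The 77 cytosolic ribosomal protein genes had a median of 0.23 (adjusted p 9.65e-08, none adjusted over the list alone) and the 51 replication-dependent histone genes a median of -0.19 (adjusted p 9.91e-06, none adjusted over the list alone). Both had an adjusted p = 0.803 with an estimated correlation. The 10 metallothioneins, metal-binding proteins, had a median of 0.76 (adjusted p 9.34e-05), with 7 up adjusted over the list alone and none over all genes, such as MT2A at 0.93 ± 0.28. Their adjusted p = 0.708 with an estimated correlation. The tumour medians were 0.34, 0.43 and 0.43 in tumours 1, 2 and 3 and 1.12 in tumour 4, which had most of the weight. Imprinted genes had a median of 0.34 (adjusted p 0.000206, 3 up adjusted over the list alone) and mesenchymal genes 0.28 (adjusted p 0.00492, 1 up adjusted over the list alone), and both had an adjusted p = 0.642 with an estimated correlation. The tumour medians of these lists averaged 0.25 ± 0.02 and 0.19 ± 0.03, and all 4 combination tumours lay below the fitted median in both. Cholesterol synthesis genes had a median of 0.22 (adjusted p 0.0414, 1 up adjusted over the list alone, adjusted p = 0.883 with an estimated correlation), against a mean of tumour medians of -0.00 ± 0.18. Fry called none of these 7 lists and instead 2 others, both up: germ-cell and meiosis genes and the promoter-methylation list (adjusted p 0.0200 each), with fitted medians of 0.17 and 0.19. Here too all 4 combination tumours lay below the fit, with tumour medians that averaged 0.12 ± 0.03 and 0.09 ± 0.03. In the germ-cell list none of 10 members passed, and in the promoter-methylation list none of 40.

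Proliferation genes were not called against the pool in the combination tumours (fitted median -0.08, adjusted p 0.0919), but this depended on the weights, which include the azacytidine tumours. Their medians were -0.54, -0.64, -0.65 and -0.07 in combination tumours 1 to 4, a mean of -0.48 ± 0.28. With tumours weighted equally the list was called lower (median -0.49, adjusted p 2.48e-09). That camera test treats levels that share arrays and the pool as independent. Without combination replicate 4 the list was called higher (median 0.54, adjusted p 0.0236), opposite in sign to the levels of the 3 tumours left. No array then sets a combination tumour against the pool.

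Combination tumour 4 carried 57.9% of the weight of its group in this test and tumour 1 27.1%, and azacytidine tumours 1 and 4 entered with weights of 26.7% and -26.7%. Between 1 and 5 genes were called without any one of aza replicates 1, 3 and 4 or of the 4 combination replicates, 27 without aza replicate 2, 28 with slide terms, 1 with median centring and 0 with Agilent processed signals, where limma had 1901 at an unadjusted p under 0.05. The ribosomal, histone, metallothionein and cholesterol lists lost their calls with slide terms and without combination replicate 4. The cholesterol list lost its call in 7 of 14 settings, also without aza replicates 1, 2 and 3 and with tumours weighted equally, the ribosomal list also with median centring, and the mesenchymal list without aza replicate 4 or combination replicate 1. Separate channels ended the calls of the ribosomal, histone, imprinted, mesenchymal and cholesterol lists. The histone median turned to 0.13 with slide terms and to 0.17 without combination replicate 4, the metallothionein median to -0.06 with slide terms and the cholesterol median to -0.01 with tumours weighted equally. With slide terms or without combination replicate 4, no array sets a combination tumour against the pool. The pool is then reached only through array 1 and the azacytidine tumours. The histone medians of the 4 combination tumours themselves were -0.31 to -0.25. Only array 9 lay on a slide that holds both the pool and a combination tumour, so no within-slide value exists.

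Between the treatments, the lists of proliferation, histone, neuronal and hypoxia genes were lower in tumours given MS-275 as well as azacytidine than in tumours given azacytidine alone, and those of epithelial, antigen-presentation and p53-target genes higher, by camera with a preset correlation. In all but the proliferation list most members did not pass in the direction of the list, and 0 lists were called with an estimated correlation. S100A14, an epithelial calcium-binding protein gene (chromosome 1, 151853630 to 151853689), was 5.03-fold higher (log2 fold change 2.33 ± 0.43, adjusted p 0.0187), at 1.47 ± 0.59 over the pool against -0.65 ± 0.24 (SD, n = 4 each). CSTA, KRT15 and CEACAM5, genes of epithelial cells, rose by 1.96 ± 0.35, 1.92 ± 0.42 and 1.83 ± 0.36. STMN2, a neuronal microtubule regulator gene (chromosome 8, 80729965 to 80730024), was 13.1-fold lower (-3.71 ± 0.62, adjusted p 0.0169). Its tumour mean was -0.81 ± 0.93 in the combination tumours and 2.96 ± 0.69 in the azacytidine tumours. IGF2, GAL and NEFM were at -3.31, -3.14 and -3.13 (all called). In total 2491 of 13994 genes changed, 1081 up and 1410 down, and in 2489 of them the 4 tumours of one treatment did not overlap the 4 of the other. Over all genes 45.0% did not overlap. Chance gives 2.86% for exchangeable levels, but neighbours in the loop share arrays, so the share with no effect is not known here.

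Proliferation genes had 33 of 47 measured members down and none up in this comparison, with a median log2 fold change of -0.90 (adjusted p 3.01e-14, 40 down adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). The tumour medians over the pool averaged -0.48 ± 0.28 in the combination and 0.52 ± 0.34 after azacytidine. MCM5, of the replicative helicase, fell by 1.55, NDC80 was at -1.57 ± 0.28 and GINS2 at -1.85 ± 0.33. Replication-dependent histones had 20 of 51 members down and 1 up, with a median of -0.34 (adjusted p 5.62e-07, 23 down and 1 up adjusted over the list alone), and the adjusted p = 0.535 with an estimated correlation. H1-5, a linker histone gene, was called lower, with 2 of 8 combination channels well above background. Neuronal genes had 16 of 35 down and 2 up, with a median of -0.47 (adjusted p 6.00e-05, 20 down and 3 up adjusted over the list alone). Their adjusted p = 0.535 with an estimated correlation, and CHGA was at -1.93 ± 0.28 (called). Hypoxia and glycolysis genes had 14 of 40 down, with a median of -0.33 (adjusted p 0.00388, 18 down adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). The tumour medians over the pool averaged 0.19 ± 0.08 in the combination and 0.31 ± 0.09 after azacytidine, a smaller difference than the fit. LDHA, a lactate dehydrogenase gene, fell by 0.95 and CA9, a carbonic anhydrase gene, fell by 1.02. Oxidative phosphorylation genes had 9 of 56 down, NDUFS7 at -0.52 ± 0.10 among them, with a median of -0.16 (adjusted p 0.00286, 8 down adjusted over the list alone, adjusted p = 0.547 with an estimated correlation). The hypoxia and oxidative phosphorylation lists lost their calls without aza replicate 4 and without combination replicate 1, where the median of the oxidative phosphorylation genes turned to 0.09 and 0.06.

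Epithelial genes had 13 of 30 measured members up and none down, with a median log2 fold change of 0.58 (adjusted p 7.32e-09, 16 up adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). The tumour medians over the pool averaged 0.28 ± 0.12 in the combination. EPCAM, an adhesion molecule gene, rose by 1.57 ± 0.32, and the claudin genes CLDN3 and CLDN7 rose by 1.25 ± 0.21 and 1.03 ± 0.15. Of 29 p53 target genes, 11 rose and none fell, with a median of 0.38 (adjusted p 0.000334, 13 up and 1 down adjusted over the list alone), at an adjusted p = 0.535 with an estimated correlation. PHLDA3 rose by 0.88 ± 0.16, and the p53 list lost its call without aza replicate 4. Class I antigen-presentation genes had 5 of 22 up, with a median of 0.37 (adjusted p 0.00109, 8 up adjusted over the list alone, adjusted p = 0.536 with an estimated correlation). PSMB9 rose by 1.26 ± 0.21 and HLA-F by 1.04 ± 0.26. Class II genes had 1 of 8 up, HLA-DMA at 1.14 ± 0.20, with a median of 0.71 (adjusted p 0.0148, 4 up adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). The class II tumour medians averaged -0.09 ± 0.02 in the combination and -0.49 ± 0.27 after azacytidine. The class I call was lost without combination replicate 4, and the class II call without combination replicate 4, without aza replicate 1 and with slide terms.

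Some markers that host cells could contribute moved with the epithelial genes. Of 13 lung epithelium markers 3 rose, PIGR at 1.56 ± 0.33 among them (median 0.29, adjusted p 0.00579, 5 up adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). Of 6 myeloid markers 2 rose, LYZ at 1.97 ± 0.51 and CD14 at 0.67 ± 0.16 (median 0.26, adjusted p 0.0125, 3 up adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). The 3 measured erythroid markers had a fitted median of 2.27, none passed, and they were too few for a list test. Their medians over the pool were 1.82, 1.32, 0.96 and -2.57 in combination tumours 1 to 4 and -3.08 to -0.43 in the azacytidine tumours. Immediate early genes had 6 of 23 up, FOS at 0.89 ± 0.21 and MYC at 0.81 ± 0.12 among them (median 0.38, adjusted p 0.0202, 8 up and 1 down adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). Heat shock and unfolded-protein genes had 6 of 29 up, PDIA4 at 0.51 ± 0.09 among them (median 0.27, adjusted p 0.0148, 8 up adjusted over the list alone, adjusted p = 0.535 with an estimated correlation). Cholesterol synthesis genes had 4 of 24 up, DHCR7 at 0.73 ± 0.13 and the regulator gene SREBF2 at 0.46 ± 0.09 among them (median 0.36, adjusted p 0.00315, 5 up adjusted over the list alone, adjusted p = 0.587 with an estimated correlation), with tumour medians that averaged -0.00 ± 0.18 against -0.17 ± 0.13. Metallothioneins had none of 10 up (median 0.54, adjusted p 0.0172, none adjusted over the list alone, adjusted p = 0.587 with an estimated correlation). Each of these 6 called lists lost its call without at least 1 tumour. The heat shock and metallothionein lists lost theirs with median centring, the myeloid and metallothionein lists with slide terms, and the immediate early list with Agilent processed signals. The metallothionein median turned to -0.10 with slide terms, to -0.12 within the second slide and to -0.12 without aza replicate 1.

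Of the genes fixed in advance, CDKN2A fell by 2.07, DNMT3A fell by 1.13, DNMT1 fell by 0.90 and HDAC2 fell by 0.75 in the combination against azacytidine. BIK, a pro-apoptotic gene, at 1.05 ± 0.32 (adjusted p 0.0528) and CDKN1A, a cyclin-dependent kinase inhibitor gene, at 0.91 ± 0.28 (adjusted p 0.0575) did not pass. Nor did DNMT3B at -0.53 ± 0.19, HDAC1 at 0.16 ± 0.09, HDAC3 at 0.12 ± 0.09 and BCL2L11 at 0.15 ± 0.09. The genes of the histone deacetylase inhibitor list went both ways, 4 of 22 up and 7 down (adjusted p 0.852, 5 up and 7 down adjusted over the list alone). SAT1, of polyamine breakdown, rose by 1.08 ± 0.18, while DHRS2, a reductase gene, fell by 1.92.

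Azacytidine tumour 4 and combination tumour 1, which share an array, carried 53.8% of the weight of their groups in this test. Azacytidine tumour 1 and combination tumour 4 carried 31.2%. The array of the first pair is the only one that holds both treatments, so values with slide terms rest on it. By limma 0 genes were called without aza replicate 4 (3479 at an unadjusted p under 0.05), without combination replicate 1 (4493), with slide terms (3688), within the second slide alone (3346) and with median centring (2536). Of the other settings, 55 were called without combination replicate 2, 621 without combination replicate 3, 13 without combination replicate 4 and 6371 without aza replicate 2. There were 5312 with separate channels, 6259 with tumours weighted equally and 3985 with tumours that share a code averaged. The last 2 counts treat loop levels that share arrays as independent. Agilent processed signals gave 599, no background subtraction 954, and azacytidine tumours 2 and 3 as 1 sample 457.

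**Figure D2:**
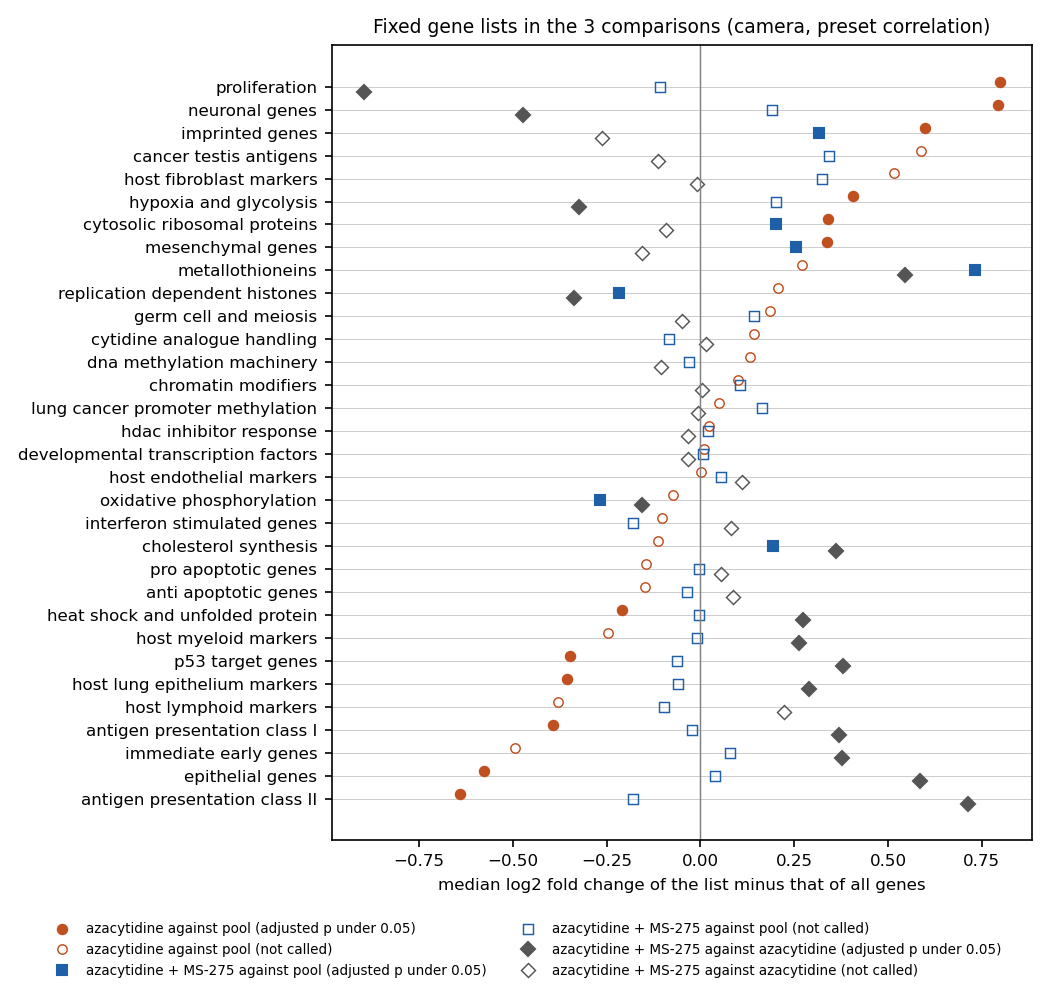
Median log2 fold change of each of 32 fixed gene lists minus the median of all genes (x axis) in the 3 comparisons, distinguished by colour and shape. Filled symbols mark lists called by camera with a preset correlation. Proliferation genes lay at 0.80 for azacytidine against the pool and at -0.90 for the combination against azacytidine.

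The 2 treatments' fold changes against the pool correlated across genes with r = 0.616 and a covariance of 0.0977. The r was 0.297 with tumours weighted equally and ran from 0.188 to 0.828 when 1 tumour was left out. Both fold changes use the same pool. Simulated data with no effect gave r = 0.579 and a covariance of 0.0212 on average over 20 simulations. The observed covariance was 0.0764 higher. Each fit also drew on tumours of the other treatment, with weights of 26.7% and -26.7%, which data with no effect cannot reflect. The excess covariance therefore does not show a shared response. The 1 pool cannot be split, so no independent controls are available for the 2 comparisons. Among called genes 3 rose in both comparisons with the pool (1.11 if the calls were independent), 6 fell in both (0.639) and 0 went opposite ways. HSD17B2 was at -2.65 and -2.63. Of the genes that rose after azacytidine, 1167 fell in the combination against azacytidine (261 if independent), and of those that fell, 560 rose (115 if independent). These counts share the azacytidine tumours and are not independent evidence.

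**Figure D3:**
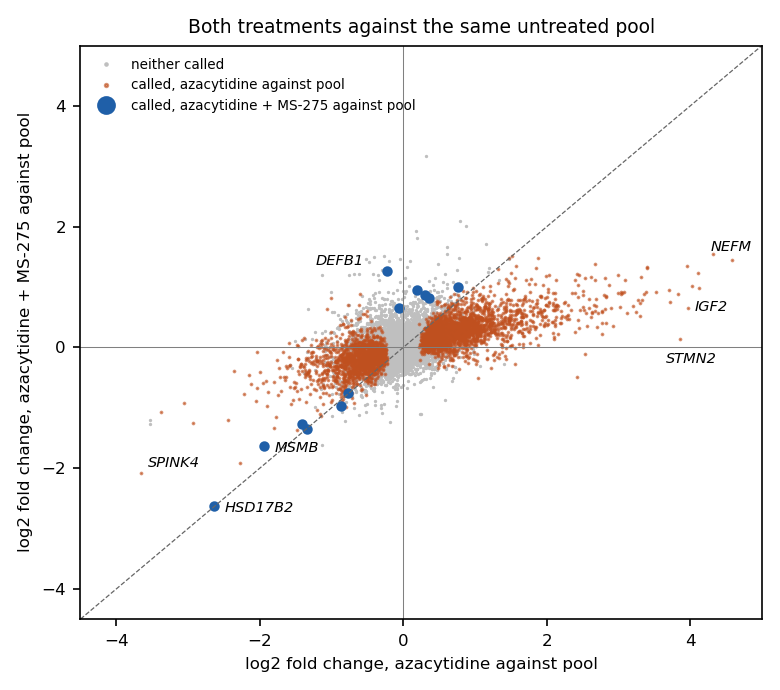
Log2 fold change of azacytidine against the pool (x axis) and of azacytidine plus MS-275 against the pool (y axis), 1 point per gene. Orange points were called for azacytidine, blue circles for the combination, and the dashed line marks equal values. NEFM lay at 4.58 on the x axis, far from the dashed line, and HSD17B2 lay close to it at -2.65 and -2.63.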

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

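All tests of explanations in this part were chosen after the results were seen. Of 316 sets of 4 tumours examined (125 genes and 33 list medians in each treatment), 40 held 1 tumour apart from the other 3 by Dixon's criterion. Chance gives about 1 in 20 for independent values in unselected sets. Here the levels share arrays and the genes were picked after their values were seen, so that rate does not apply. In 22 of the 40 the tumour apart was azacytidine tumour 1 and in 16 it was combination tumour 4, the 2 tumours hybridised beside the pool. All levels are log2 over the pool.

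Azacytidine tumour 1 lay above the other azacytidine tumours for several single genes, some of them members of tested lists. NEFM was at 4.79 against 3.27 to 3.37, IGFBP5 at 4.29, SCG3 at 2.69, MAGEL2 at 3.11, MDK at 3.44 and VWF at 2.07. Azacytidine tumour 1 was also higher for GINS2 at 2.13, HK2 at 2.90, DNMT1 at 1.34, HDAC3 at 0.18 and H1-5 at 1.51. It lay below the others for CLDN18 at -2.34, ESRP2 at -1.67, FDXR at -1.38, KRT15 at -1.22, TAP1 at -1.24, PSMB9 at -1.24, HLA-F at -0.94, BAG3 at -0.47, SOX17 at -0.44, H1-2 at -0.14 and the median of oxidative phosphorylation genes at -0.16.

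Combination tumour 4 lay above the other combination tumours for the cell-cycle genes GINS2 at 0.0382 against -0.68 to -0.64 and NDC80 at 0.0749, for the germline genes CSAG2 at 0.90, CSAG1 at 0.98 and MAGEB2 at 0.64, and for PDK1 at 0.56, TIMP3 at 0.21, HOXD10 at 0.95 and MDK at 0.75. The metallothioneins MT2A at 1.30, MT1X at 1.35 and MT1A at 1.05 were higher in it too, as were the list medians of metallothioneins at 1.12 and of hypoxia and glycolysis genes at 0.30. It lay below the others for FOS at 0.28 and SAT1 at 0.38. PPP1R1C was lowest in combination tumour 2, at 0.75, and SGCE in combination tumour 3, at 0.29.

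The count of genes called for azacytidine against the pool went from 4077 to 0 without azacytidine tumour 1 (2825 at an unadjusted p under 0.05 in limma), so that tumour alone is a candidate explanation. Against this, 1497 genes that differed at least 2-fold between it and the pool on the array they share were followed in azacytidine tumour 4 over the pool through arrays 5 to 9, which hold no RNA of tumour 1. Their median share of the first ratio was 0.397 (bootstrap SE 0.0144 over genes, which are not independent), with 85.4% on the same side. In combination tumour 1, from arrays 6 to 9, which share the same pool, it was 0.00400, with 50.8% on the same side. This test replaced the share of the fold change kept by called genes, 0.777, since those fits share arrays and the genes were picked on them. The median standard error of all genes went from 0.130 to 0.210 without it, since 1 of the 2 arrays with the pool leaves the loop, and the calls ended with this wider error and smaller changes. Lower precision stays open, since a test of it was dropped after its value was seen. A changed share of rat host cells of all types could not be settled: fibroblast markers lay 0.57 above lung epithelium markers in the azacytidine tumours, with a bootstrap SE of 0.42, and tumour cells can express both. This marker test replaced a block test whose value had been seen. A direct effect of azacytidine stays open, since 1 pool carries all untreated tumours.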

How the results depend on the processing

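No result kept its value under every alternative. In each comparison at least 1 alternative called 0 genes, so no gene could keep its call in all of them. Among the 61, 12 and 53 called genes examined one by one, 0 changed direction. Over all 295 genes of the rule 7 did, DNAJA4 and HLA-DOA with the mean of a gene's probes, NSDHL, DNAJB1 and RPS21 with median centring, COL6A3 without azacytidine tumour 1 and KDR without azacytidine tumour 4. Weighting tumours equally, counting azacytidine tumours 2 and 3 as 1 sample and taking each slide alone were chosen after the data were seen. Except where the construction shows it (fewer tumours or arrays), the cause was not tested.

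For azacytidine against the pool (4077 genes), 2595 were called with Agilent processed signals, 1752 with median centring (90.6% of them up), 5 with separate channels, 1364 with tumours that share a code averaged and 1294 with equal weights; leaving out 1 tumour gave 0 (without azacytidine tumour 1) to 5530. Median centring moved the median of all genes by 0.32, against 0.14 for the combination against the pool and -0.20 between treatments. The other alternatives gave 2863 to 5500, with 5220 within the first slide, where array 1 alone holds the pool.

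For the combination against the pool (12 genes), limma called 0 with Agilent processed signals (1901 at an unadjusted p under 0.05), 2 without background subtraction and 1 with median centring. It called 20 without a detection filter, 5 with detection in all 9 RNAs, 7 with separate channels, 31 without a dye term and 6 with codes averaged. With the pool given the variance of a mean of 4 tumours 46 were called, and 4 with azacytidine tumours 2 and 3 as 1. With slide terms, where no array sets a combination tumour against the pool, 28 were called. Leaving out 1 tumour gave 1 to 27.

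For the combination against azacytidine (2491 genes), 599 were called with Agilent processed signals, 954 without background subtraction, 5312 with separate channels, 3985 with codes averaged, 457 with azacytidine tumours 2 and 3 as 1 and 6259 with equal weights. Limma called 0 with median centring (2536 at an unadjusted p under 0.05), with slide terms (3688) and within the second slide (3346). Leaving out 1 tumour gave 0 (without azacytidine tumour 4 or combination tumour 1) to 6371. With the number in the codes as a replicate block 1774 were called, but tumours that share a number did not deviate alike (r across genes from -0.40 to 0.27), so the numbers were not taken as pairs.

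Lists called with the preset correlation (12, 7 and 15) went to 0, 0 and 0 with an estimated correlation; for the combination against the pool 2 were called by fry and 4 with separate channels. The correlation of both fold changes (0.616) was 0.237 with separate channels, 0.297 with equal weights and 0.188 to 0.828 leaving out 1 tumour. The spread between tumours (0.118 and 0.0974) ran from 0.0674 without azacytidine tumour 1 to 0.233 with processed signals for azacytidine, and from 0.0773 without combination tumour 4 to 0.224 with median centring for the combination. Signal limits genes near background, such as FABP1, to a bound.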

Other observations

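The tests of chromosome blocks were chosen after the result was seen; the counts of other splits were planned. Further genes moved outside the groups described. Developmental transcription factors went both ways after azacytidine, 22 of 75 up and 13 down (camera adjusted p 0.753), with HOXD10 at 2.82 ± 0.37 and DLX1 at 3.83 ± 0.57 up and IRX2 at -1.02 ± 0.14 down. Immediate early genes had 4 of 23 up and 7 down (adjusted p 0.0964), and NR4A1 fell by 0.92 and MYC fell by 1.12. This list was called lower without azacytidine tumour 1 (adjusted p 0.0173) and with median centring (adjusted p 0.0116), and replication-dependent histones, not called in this comparison, were called higher in 8 settings, such as slide terms (adjusted p 0.00572). The endothelial marker VWF rose by 1.65 ± 0.35 in a list with 2 of 11 up and 1 down (adjusted p 0.786). The erythroid marker HBA1 was at -3.54 ± 1.38 after azacytidine and did not pass (adjusted p 0.0825). Interferon-stimulated genes had 5 of 40 up and 4 down (adjusted p 0.302), but were called lower with slide terms (adjusted p 0.00572), within the first slide (adjusted p 0.0146) and without azacytidine tumour 4 or combination tumour 1 or 4. In each of these settings only array 1, which holds azacytidine tumour 1, links the azacytidine tumours with the pool. The list medians were -0.27 in azacytidine tumour 1 and 0.03, 0.02 and 0.14 in tumours 2, 3 and 4. Against azacytidine alone, the combination tumours had higher CD70, a TNF family ligand gene, by 1.70 ± 0.20, and TFPI2, a protease inhibitor gene, by 1.02 ± 0.14, and lower ONECUT2, a homeobox gene, at -2.92 ± 0.36.

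Genes outside the rule were chosen because of their values, so that their order of groups adds no support to the pattern. SMARCA4, a chromatin remodelling ATPase gene, was at 3.61, 2.61, 2.31 and 1.97 over the pool in azacytidine tumours 1 to 4 and at -0.41, -0.18, -0.40 and 1.07 in combination tumours 1 to 4. HMGA2 averaged 2.29 ± 0.63 in the azacytidine tumours and -0.33 ± 0.50 in the combination tumours, and NES averaged 2.22 ± 0.51 and 0.26 ± 0.52 (SD, n = 4).

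Neighbouring genes shifted together along the chromosomes. In 124 blocks of 100 genes in hg18 order, the medians for azacytidine against the pool had a standard deviation of 0.101, against a mean of 0.0652 over 1000 shuffles of runs of 20 genes (permutation p 0.001, the smallest that 1000 shuffles can give). On chromosome 13 from 46249745 to 107659297 the median was 0.45, with 73% of the genes up and tumour medians of 0.57, 0.40, 0.35 and 0.20, and on chromosome 20 from 205708 to 18245522 it was -0.25. Azacytidine tumour 1 alone is argued against. Over blocks, the ratio of azacytidine tumour 4 over combination tumour 1 had a slope of 0.301 (bootstrap SE 0.0307) on the ratio of azacytidine tumour 1 over the pool, from 2 arrays with no RNA in common and opposite dyes. Azacytidine acting alike in both treated groups is argued against too, for the mean of the combination tumours. The slope of their mean block medians on those of the azacytidine tumours was 0.0615 (bootstrap SE 0.0339). Combination tumour 4 differed: over blocks its r with the azacytidine tumours was 0.307 to 0.518, against -0.126 to 0.204 for combination tumours 1 to 3. These r share the pool, and no slope was computed for tumour 4 alone. An effect of azacytidine that MS-275 removes stays open.

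A hypothesis is that the RNAs may hold different shares of human cell populations that differ in copy number. The spread of block medians exceeded the shuffles for azacytidine against the pool and for the combination against azacytidine (permutation p 0.001 each), but it also did for the combination against the pool (0.001), where no mixing was proposed, and for each tumour (0.001 to 0.01). The comparison of the combination with the pool was added as a control after the other values were seen. It is not free of the azacytidine tumours, since tumours 1 and 4 entered that fit with weights of 26.7% and -26.7%. The loop levels of the single combination tumours do not use these weights, and each gave a permutation p of 0.001 to 0.01. The test therefore does not separate a mixed sample from co-expression of neighbouring genes, and these explanations cannot be told apart here. Shuffling single genes had first given 0.001 for all sets, which is why runs of 20 genes were shuffled, and the slope of the combination tumours replaced a correlation of block medians (r = 0.162) that shares the pool. The slope from 2 arrays replaced a permutation p without azacytidine tumour 1 (0.001), low in every set, and a slope from loop levels (0.495) that array noise alone puts at 0.429. No copy number was measured.

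The ratios of array 3, azacytidine tumour 2 against tumour 3, had a standard deviation of 0.0885 over detected probes, and the other arrays 0.158 to 0.592. The labels give these RNAs different names and codes, but whether they are separate tumours was not tested. If they are not, n = 4 is 3 for azacytidine throughout. Of the 35 splits of the 8 treated tumours into 4 and 4, 1, the real one, called 2491 genes. The highest of the others called 2. Every other split mixes the treatments, which widens the error, and each tumour has a fixed place and weight in the loop. The tumours are thus not exchangeable, and the count of genes cannot exclude chance. The splits ignore the shared codes, and the real split largely follows the slides, so they do not exclude a difference between slides. With slide terms 0 genes were called, but only array 5 then sets the treatments against each other. That count therefore cannot tell a difference between slides from lost precision. For lists also 1 of 35 reached the real count of 15, but others called up to 14, so the count of lists sets the real split apart by 1 list only.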
